A study of Arabidopsis thaliana with 36 samples.

How the data were processed

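Gene expression was measured by RNA sequencing in source leaves, sink leaves, rosette buds and flowers of Arabidopsis Col-0 wild type and of plants labelled triple and quintuple S1 bZIP mutant, with 3 biological replicates per group and 36 libraries in all. Per the labels' protocols, plants grew in long days (16 h light and 8 h dark, 60% humidity, 100 µmol per square metre and second) until flowering began, and poly-A libraries were made with a stranded kit from 500 ng of total RNA. The deposited values are raw counts per locus, per the file headers, in 8 tables of 28775 loci, 1 table per mutant and tissue with the wild-type libraries of that tissue in each. Per the submitters' processing notes, Salmon 0.7.2, SAMtools 0.1.18, R 3.5.1, edgeR, DESeq2 and the TAIR10 build were used, and no role is given for any of them. Whether the counts are rounded estimates or counted reads, and whether counting used the strand, is not given in the sources used here. The tissue of each column was taken from the table it stands in. All values were whole numbers, and the lowest and highest library totals were 18158887 and 25124369. No library was a copy of another in its group, with a lowest chi-square per gene of 5.83 between replicates. Between genotypes of a tissue only correlations were computed (highest 0.983), and libraries of different tissues were not compared in this way.

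Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and summarised in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. CPM values were computed here from the deposited counts with TMM scaling among the libraries of each comparison, so those of wild type differ between comparisons. Genes were kept by filterByExpr and tested with edgeR quasi-likelihood F tests (estimateDisp, glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. No minimum fold was set, and counts of genes changed at least 2-fold stand beside the others. Each mutant was compared with wild type in the 6 libraries of its table. The mutants were compared with each other in a model of the 9 libraries of a tissue, in which the 3 genotypes share 1 spread per gene. Differences between tissues were tested with the 3 genotype by tissue terms of a model of 24 libraries per mutant, and wild-type sink and source leaves within the 12 wild-type libraries. The SE of a log2 fold is its size divided by the square root of the F value. Where a group had no counts, a lower limit of the fold was computed with a floor of 3 counts in that group, and where it had 1 to 3 counts, a count ratio with a 95% interval.

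Gene lists (32 lists, 439 memberships, 430 loci) were written before the data were examined. They covered S1 bZIP and C group bZIP genes, clade III and other SWEET genes, sugar carrier, sucrose cleavage, trehalose pathway and starch genes, nitrogen metabolism and transporter genes, low energy markers, branching, meristem and cell cycle genes, and auxin, cytokinin, abscisic acid, immune and jasmonate genes. Flavonoid, photosynthesis, senescence, seed storage, phosphate, iron, clock, heat shock, handling, floral identity, tapetum, pollen and vascular genes completed them. Clock, heat shock and handling genes were listed to mark the harvest, and harvest differences between genotypes were not tested as a cause. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over all lists and the 8 comparisons with wild type, with an estimated correlation and fry beside it. Members past the threshold were counted over all genes and again with the adjustment run over the list alone. Of the 28775 loci 28009 stood in the reference gene table and 10588 had a symbol. Because the table gives their loci other names, 5 list members (TST1, TST2, TST3, EXO-L and HSP70-4) were left out. About 16 genes and some counts of calls with replicate blocks had been looked at before this name check, none of the left-out members among them.

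Genes were named by a rule fixed in advance. Named in each comparison with wild type were the 5 S1 bZIP genes, the 7 clade III SWEET genes, GAT1_2.1, ASN1, PRODH1 and BRC1. Added to these were the 6 largest rises and 6 largest falls among passing genes whose mutant libraries all lay on one side of the wild-type libraries and whose higher group had at least 2 CPM, and up to 4 members with the smallest p of each list that passed or had at least 3 passing members. For each mutant up to 10 genes that passed in the same direction in all 4 tissues were added, smallest of the largest p first, with ties ordered by locus (a detail set after the values were seen, to make the choice repeatable). In the comparison of the mutants the rule named the 4 largest rises and falls, for differences between tissues the fixed genes and the 5 smallest p values per mutant, and for wild-type leaves the lists only. The text names a part of the genes the rule allows.

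The tests were run on simulated counts, with 200 genes changed by known folds. Counts were drawn from gene means over mutant and wild-type libraries together and from the library sizes and fitted spread of the real libraries. Of genes changed 4-fold, 96.9%, 97.0%, 93.8% and 100% were recovered in triple mutant flowers, buds, sink and source leaves, and 83.1%, 77.3%, 80.6% and 75.8% in the quintuple mutant. At 2-fold the shares were 85.1%, 66.7%, 77.6% and 80.0%, and 14.3%, 7.5%, 18.2% and 24.2%. At 1.5-fold they were 58.2%, 41.8%, 14.9% and 20.9% in the triple and 0%, 1.5%, 4.5% and 0% in the quintuple mutant. The tests of differences between tissues recovered 83.4% and 58.9% of 4-fold changes. More genes passed in the real comparisons with wild type (464 to 8387), which loosens the adjusted threshold, so these shares hold for the simulated tests only. Replicates correlated at 0.979 to 0.991 in wild-type and triple mutant groups, and at 0.923 to 0.977 in quintuple mutant flowers and 0.913 to 0.980 in quintuple mutant buds.

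Calls shared by the mutants were set beside the number expected from independent calls and beside 5 simulations per tissue in which unchanged mutants were compared with the same simulated wild-type libraries. All simulated libraries had the spread fitted over the 9 libraries of the tissue, and genes were drawn independently. The simulation was corrected once, after the observed leaf shares had been seen, because it had first drawn the mutants around the observed wild-type mean. Comparisons of 3 with 3 libraries were repeated for all 10 splits of the libraries, and the tissue tests for 30 drawn splits. Alternatives were DESeq2 size factors, DESeq2 itself, no low count filter, replicate blocks, each library left out in turn, no chloroplast and mitochondrial genes, all 9 libraries of a tissue in 1 model, the 6 mutant libraries alone, other list tests and windows of 0.2 and 3 Mb around the S1 loci in place of 1 Mb. Added after the data were seen were the all-tissue gene counts under these settings, and bud and leaf gene levels in flowers without the low count filter. The quintuple mutant shares of such genes above wild-type flowers had first counted genes under the filter as not above (11.1% for buds, 75.0% for leaves) and were corrected to cover all of them. These genes were chosen by CPM scaled among the 12 wild-type libraries, and their levels were then scaled by library totals. Several named genes overlap a neighbour over at least 25% of their length, so their counts may hold reads of it, among them GAE4 (99.6%), F3H (94.5%), AMT1.1 (81.1%), EC1.1 (46.9%), SHP2 (45.0%), GAT1_2.1 (36.5%), KN (31.4%), SHT (26.1%) and LHCB6 (25.2%). The PDF1.2, LHCB1 and RBCS families hold near-identical genes. Sequence reads were not analysed here.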

Results

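Transcript counts were collected from source leaves, sink leaves, rosette buds and flowers of Arabidopsis Col-0 wild type and of plants labelled as triple and quintuple mutants of S1 group bZIP transcription factors. There were 3 biological replicates per genotype and tissue, 36 libraries in 12 groups, with totals between 18158887 and 25124369 counts per library. The comparisons asked how genes of carbon and nitrogen supply, of branching and of organ growth stood in each mutant in organs that export sugar and in organs that import it. The labels do not name the mutated genes or alleles, and counts per locus cannot check them, so the plants are described here as the libraries labelled triple and quintuple mutant. Values are library-scaled counts (CPM) as mean ± SD and log2 folds ± SE, with n = 3 in each group. CPM was scaled among the libraries of each comparison, so the same wild-type group has somewhat different values in different comparisons. Adjusted p values are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and only genes under 0.05 are said to have risen or fallen. For any single gene, 3 libraries lie wholly beyond 3 others by chance in 10% of groupings. Gene lists were tested with camera at a preset correlation. No list passed in any mutant comparison with wild type when the correlation was estimated from the data, and those p values stand beside each list that passed with the preset one. Named genes follow a rule fixed in advance unless stated otherwise.

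In wild-type plants known marker genes separated flowers and rosette buds from leaves, while sink and source leaves are told apart here by the deposited table they stand in. The petal and stamen identity gene AP3 (AT3G54340) stood at 60.4 ± 3.00 CPM in flowers, 3.68 in rosette buds, 0.0196 in sink leaves and 0.0402 in source leaves. BRC1 (AT3G18550), which encodes a TCP factor that restrains axillary bud outgrowth, stood at 20.6 CPM in buds, 2.43 in flowers, 0.328 in sink leaves and 0.284 in source leaves, in the scaling of the 12 wild-type libraries.

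**Figure D1:**
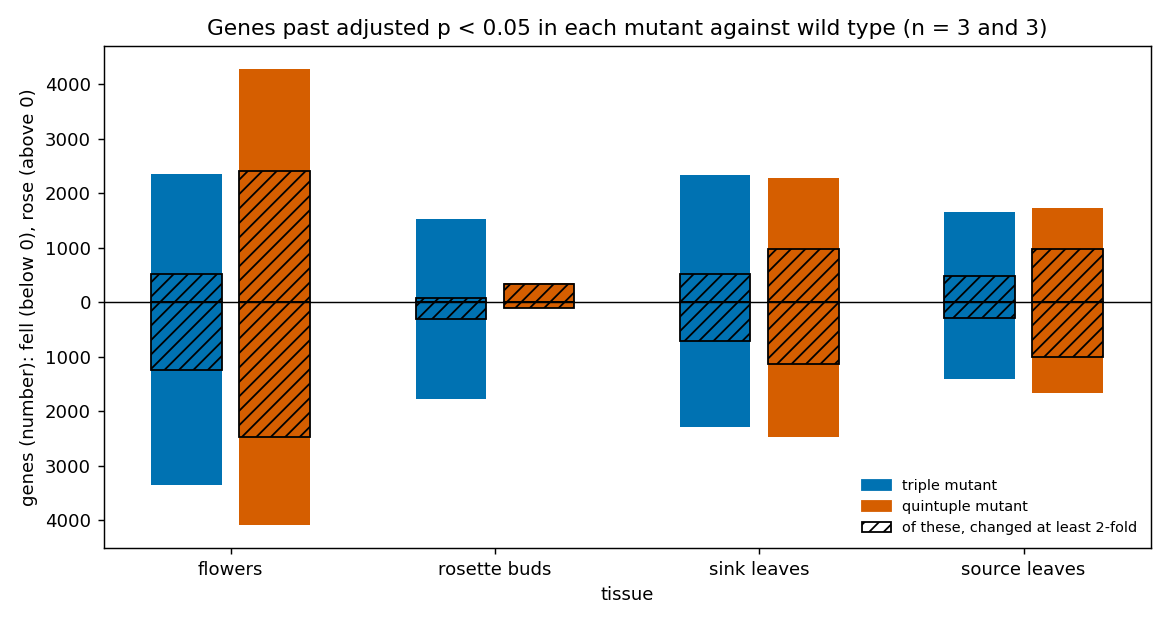
Genes past an adjusted p of 0.05 in each mutant against wild type, drawn above 0 where they rose and below 0 where they fell, with hatching for those that changed at least 2-fold (n = 3 and 3). Flowers had 5711 such genes in the triple and 8387 in the quintuple mutant, and rosette buds had 3298 and 464. At least 2-fold, buds had 80 rises and 310 falls in the triple and 332 and 101 in the quintuple mutant. DESeq2 gave 3639 and 4026 genes in buds, and edgeR gave 10874 without quintuple mutant replicate 1.

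Triple mutant flowers were compared with wild-type flowers to ask which supply and organ genes stood differently at the apex. Among the S1 genes, bZIP11 (AT4G34590), a regulator of amino acid and trehalose metabolism, fell from 220 ± 11.7 to 128 ± 16.7 CPM (log2 -0.78 ± 0.10, adjusted p = 0.000358). bZIP44 (AT1G75390) also fell (-0.56 ± 0.08), bZIP2 (AT2G18160) rose (0.44 ± 0.07), and bZIP1 (AT5G49450; -0.24 ± 0.15) and bZIP53 (AT3G62420; 0.20 ± 0.09) did not pass. The sucrose exporters of SWEET clade III separated by gene. SWEET10 (AT5G50790) fell from 121 ± 10.2 to 46.8 ± 2.72 CPM, SWEET15 (AT5G13170) from 54.5 ± 13.7 to 20 ± 5.47, SWEET14 (AT4G25010) from 63.6 ± 4.88 to 28.2 ± 12.4, SWEET13 (AT5G50800) from 60.5 ± 5.85 to 31.6 ± 11.6 and the nectary gene SWEET9 (AT2G39060) from 55.3 ± 12.6 to 28.8 ± 5.85. SWEET11 (AT3G48740; 0.39 ± 0.07) and SWEET12 (AT5G23660; 0.50 ± 0.10), known for phloem loading in leaves, rose. ASN1 (AT3G47340), PRODH1 (AT3G30775), GAT1_2.1 (AT1G15040) and BRC1 did not pass (-0.03 ± 0.10, -0.11 ± 0.15, -0.15 ± 0.15 and -0.19 ± 0.25).

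Sugar use and nitrogen transport genes of triple mutant flowers included falls and rises. The cell wall invertase CWINV2 (AT3G52600) fell from 308 ± 31.7 to 91.7 ± 11.2 CPM, SUS1 (AT5G20830) was 1.71-fold lower, and the trehalose phosphate phosphatases TPPJ (AT5G65140) and TPPF (AT4G12430) were 3.17-fold and 2.64-fold lower. The carrier STP4 (AT3G19930) rose 2.37-fold and STP14 (AT1G77210) 3.42-fold, while SUC5 (AT1G71890) was 2.02-fold lower. Sucrose cleavage genes (6 of 13 down, 2 up, camera adjusted p = 0.212) and sugar carriers (3 of 11 up, 2 down, 0.47) did not pass as lists. Amino acid carriers UMAMIT28 (AT1G01070), AAP5 (AT1G44100) and AAP4 (AT5G63850) were 2.08-fold, 1.90-fold and 1.74-fold lower, and the nitrate reductase gene NIA1 (AT1G77760) 2.49-fold lower. Of 22 measured amino acid and nitrate transporter genes 11 fell and 2 rose (camera adjusted p = 0.0197, and 0.719 with an estimated correlation), and of 18 trehalose pathway genes 9 fell and 1 rose (0.0456 and 0.719). Clade III SWEET genes had 5 of 7 lower and 2 higher (median log2 -0.94, camera adjusted p = 0.0456, and 0.685 with an estimated correlation). Senescence genes fell in 9 of 12 cases with 1 rise (10 falls adjusted over the list alone), among them SAG21 (AT4G02380; -1.71 ± 0.10) and the NAC regulator NAP (AT1G69490; -1.03 ± 0.15) (list 1.53e-05 and 0.649). Phosphate starvation genes fell in 4 of 7 cases, including MGD2 (AT5G20410; -1.57 ± 0.07) (list 0.000829 and 0.649).

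Some anther genes of triple mutant flowers stood far from their wild-type levels. SHT (AT2G19070), which encodes a tapetum acyltransferase that makes pollen coat spermidine conjugates, stood at 0.0339 CPM in wild type and 47.9 ± 30.7 in the mutant, a count ratio of 1520 (95% interval 421 to 12600). AT5G48210 had no counts in wild type and 17.9 ± 12.7 CPM in the mutant, at least 378-fold more. These intervals and floors cover counting error only. The tapetum regulator AMS (AT2G16910) rose 11-fold, SWEET8 (AT5G40260), needed for the microspore wall, rose 10.7-fold, and the pollen coat gene GRP17 (AT5G07530) rose 5.43-fold. Later pollen genes AGP11 (AT3G01700), AGP6 (AT5G14380) and VGD1 (AT2G47040) were 4.16-fold, 3.25-fold and 2.39-fold lower. Tapetum and microspore genes rose in 2 of 10 cases (median 1.84, camera adjusted p = 0.0442, and 0.926 with an estimated correlation), and mature pollen genes fell in 4 of 7 with 1 rise (median -1.26, 0.0244 and 0.827). A larger share of young flowers could give such shifts of both lists, and was not tested for the triple mutant. The synergid-expressed gene DD18 (AT1G45190) was 39.9-fold lower. Cytokinin response genes rose in 4 of 9 cases with 1 fall (0.0469 and 0.649), including ARR7 (AT1G19050; 0.97 ± 0.14) and ARR6 (AT5G62920; 0.88 ± 0.14), and photosynthesis genes rose in 10 of 23 with 1 fall (median 0.18, 0.0215 and 0.923). In the same libraries 66.7% of 12 leaf genes nearly absent from wild-type flowers lay above them, at a median of 0.856% of the source leaf level. Low energy marker genes rose in 8 of 15 cases and fell in 1 without the list passing (0.0679), among them DIN1 (AT4G35770), 2.39-fold.

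Altogether 5711 of 21476 tested genes passed in triple mutant flowers, 2353 up and 3358 down, and 522 and 1242 of these changed at least 2-fold. An analysis of all 9 flower libraries together gave 1638 genes and ended 70 of the 118 named calls.

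Quintuple mutant flowers were compared with wild-type flowers with the same question. bZIP1 rose from 6.68 ± 0.543 to 48.5 ± 22.6 CPM (log2 2.86 ± 0.33, adjusted p = 0.000996). bZIP11 fell from 218 ± 11.5 to 41.4 ± 22.6 CPM (-2.39 ± 0.39) and bZIP44 from 121 ± 3.66 to 38.6 ± 9.85 (-1.65 ± 0.19), bZIP53 rose (0.50 ± 0.16) just under the threshold, and bZIP2 did not pass (-0.34 ± 0.21). SWEET10 was 7.60-fold lower, SWEET14 4.48-fold, SWEET13 3.24-fold and SWEET15 3.23-fold lower, whereas SWEET12 rose 3.28-fold and SWEET11 1.92-fold, and SWEET9 (-1.69 ± 1.14) did not pass. PRODH1, the first enzyme of proline breakdown, was 8.10-fold lower, and ASN1 (-1.02 ± 0.42) and GAT1_2.1 (-0.61 ± 0.22) did not pass. BRC1 rose from 3.05 ± 0.585 to 28.9 ± 14.1 CPM (3.24 ± 0.38, adjusted p = 0.00108). The homeodomain genes HB21 (AT2G18550), HB40 (AT4G36740) and HB53 (AT5G66700), known targets of BRC1 in buds, rose 60.9-fold, 30.9-fold and 92.4-fold, and NCED3 (AT3G14440), an abscisic acid synthesis gene, rose 3.32-fold. Branching and bud dormancy genes rose in 11 of 22 cases and fell in 3 (13 and 4 over the list alone, median 0.90, camera adjusted p = 0.000964, and 0.649 with an estimated correlation). Shoot meristem genes rose in 8 of 13 (0.0112 and 0.746), among them SOC1 (AT2G45660) 5.50-fold and TFL1 (AT5G03840) 10-fold.

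Floral organ and reproductive genes of quintuple mutant flowers included falls and rises. The ovule gene STK (AT4G09960) was 9.82-fold lower, SHP2 (AT2G42830) 4.89-fold, SUP (AT3G23130) 4.74-fold and SHP1 (AT3G58780) 2.68-fold lower. Floral organ identity genes fell in 7 of 14 cases with 1 rise (median -0.60, camera adjusted p = 0.00218, and 0.685 with an estimated correlation). Auxin response genes fell in 5 of 8 with 2 rises (0.00643 and 0.649), IAA19 (AT3G15540) being 7.33-fold lower and IAA1 (AT4G14560) 4.83-fold, while the conjugating enzyme gene GH3.5 (AT4G27260) rose 5.23-fold. Tapetum and microspore genes rose in 8 of 10 cases, and in 10 over the list alone (median 4.01, 6.91e-05 and 0.719). AMS rose 32.7-fold, LAP5 (AT4G34850) 24.4-fold, and AT5G52160 went from no counts to 47.1 ± 11.1 CPM, at least 1000-fold. In contrast AGP11 was 7.60-fold, AGP6 6.84-fold and VGD1 5.88-fold lower, and the mature pollen list fell in 4 of 7 cases with 1 rise without passing (median -2.56, 0.0817). AT1G56100 went from 26.6 ± 6.33 CPM to no counts, at least 493-fold lower.

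Most salicylic acid and immune genes and 7 of 12 senescence genes rose in quintuple mutant flowers. SARD1 (AT1G73805), an activator of salicylic acid synthesis, rose 47.7-fold, ACD6 (AT4G14400) 7.99-fold, WAK1 (AT1G21250) 7.68-fold and PR2 (AT3G57260) 5.57-fold. Of 19 salicylic acid and immune genes 15 rose and 1 fell (median 2.31, camera adjusted p = 5.09e-08, and 0.685 with an estimated correlation). Senescence genes rose in 7 of 12, or 10 over the list alone (0.00407 and 0.883), including ORE1 (AT5G39610; 2.63 ± 0.32) and SAG101 (AT5G14930; 2.72 ± 0.23). Photosynthesis genes rose in 11 of 23 (median 0.74, 0.0195 and 0.948), RCA (AT2G39730) 1.84-fold and LHCA2 (AT3G61470) 2.08-fold. In the same libraries 83.3% of 12 leaf genes nearly absent from wild-type flowers lay above them, at a median of 4.96% of the source leaf level, and photosynthesis genes had a wild-type median of 650 CPM in flowers, 7290 in sink and 3900 in source leaves. Without their lists passing, the ammonium transporter AMT1.1 (AT4G13510) rose 4.48-fold and the nitrate transporter NRT1.8 (AT4G21680) 27.5-fold, while AAP8 (AT1G10010) was lower by a count ratio of 66.5 (18.1 to 554). CWINV2 was 7.85-fold, TPPJ 7.75-fold and SUC5 6.16-fold lower, and SUS3 (AT4G02280) rose 5.58-fold. Lists that did not pass included handling and wounding (4 of 10 up, 1 down, 0.285), jasmonate (2 of 15 up, 4 down, 0.817), iron homeostasis (0 of 6 up, 3 down, 0.665) and other SWEET genes (1 of 8 up, 3 down, 0.794).

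In all, 8387 of 21756 tested genes passed in quintuple mutant flowers, 4287 up and 4100 down, with 2413 and 2477 at least 2-fold. The balance turned in several settings, among them the leaving out of chloroplast and mitochondrial genes (3846 up and 4584 down). Single libraries left out moved the count between 5541 and 11184.

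Triple mutant rosette buds were compared with wild-type buds to ask how genes of bud rest and bud growth stood in lateral organs. None of the S1 genes passed, with bZIP2 at 0.34 ± 0.11, bZIP53 at 0.43 ± 0.13, bZIP11 at 0.24 ± 0.15, bZIP1 at -0.22 ± 0.18 and bZIP44 at -0.70 ± 0.22. BRC1 fell from 27.2 ± 2.73 to 13.7 ± 4.43 CPM (log2 -0.99 ± 0.20, adjusted p = 0.0137). Its known targets HB21 and HB40 fell from 11.6 ± 2.19 to 3.54 ± 0.564 and from 7.30 ± 2.23 to 1.64 ± 0.264 CPM, NCED3 was 5.40-fold lower, and the dormancy marker DRM1 (AT1G28330) fell from 354 ± 45.0 to 135 ± 34.9 CPM. Of 21 measured branching and bud dormancy genes 10 fell and none rose (median -0.58, camera adjusted p = 3.93e-07, and 0.649 with an estimated correlation). Abscisic acid and dehydration genes fell in 13 of 16 cases, 14 over the list alone (median -1.23, 7.55e-20 and 0.649), including RD29A (AT5G52310) 3.33-fold, HB7 (AT2G46680) 2.77-fold, KIN2 (AT5G15970) 2.33-fold and the phosphatase gene ABI1 (AT4G26080) 1.76-fold. LEA4-5 (AT5G06760), a dehydration protein gene among the largest falls, was 9.39-fold lower.

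Most division genes rose in the same buds. Of 15 cell cycle genes 12 rose, or 14 over the list alone (median 0.63, camera adjusted p = 1.58e-11, and 0.649 with an estimated correlation), with the replication helicase genes MCM5 (AT2G07690) and MCM2 (AT1G44900) up 1.72-fold and 1.68-fold and the mitotic cyclin CYCB1.2 (AT5G06150) up 1.72-fold. Cytokinin response genes rose in 6 of 10 cases (0.000852 and 0.685), ARR15 (AT1G74890) 2.52-fold and CKX4 (AT4G29740) 1.99-fold. Nitrogen transporters included falls only, with the nitrate transporters NRT2.1 (AT1G08090), NRT1.5 (AT1G32450) and NRT1.1 (AT1G12110) 14.1-fold, 3.36-fold and 2.26-fold lower, and 7 of 22 list members down with none up (11 over the list alone, median -0.63, 3.03e-07 and 0.649). Nitrate reductase NIA2 (AT1G37130) was 2.06-fold lower and ASN1, an asparagine synthetase gene, fell from 182 ± 31.9 to 113 ± 5.76 CPM. PRODH1 rose from 34.0 ± 8.80 to 80.8 ± 6.90 CPM, the glutamate dehydrogenase gene GDH2 (AT5G07440) 2.1-fold and the raffinose metabolism gene DIN10 (AT5G20250) 2.72-fold. SWEET13 was 3.32-fold and SWEET10 8.81-fold lower at low levels, and SWEET11 (-0.62 ± 0.31) and SWEET12 (0.06 ± 0.56) did not pass.

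Further lists passed in triple mutant buds, most with a minority of members down. Clock genes among them were listed to mark the harvest, and a difference in harvest time was not tested. Clock genes fell in 7 of 12 cases (camera adjusted p = 0.000333, and 0.685 with an estimated correlation), photosynthesis genes in 6 of 23 (6.16e-05 and 0.923), senescence genes in 4 of 12 (0.000579 and 0.649), and trehalose pathway genes in 7 of 18 with 1 rise (0.00407 and 0.685). Floral organ identity genes passed as a list (0.00776 and 0.879) with 1 of 11 members down, LFY (AT5G61850), 1.69-fold. The defensin genes PDF1.3 (AT2G26010) and PDF1.2 (AT5G44420), which are near-identical in sequence, rose 41.2-fold and 8.93-fold. Nitrogen and amino acid metabolism genes (3 of 27 up, 5 down, 0.945), vascular genes (3 of 11 down, 0.0642), sucrose cleavage genes (1 of 11 up, 1 down, 0.976) and S1 bZIP genes (0 of 5, 0.692) did not pass as lists.

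Of 20010 tested genes 3298 passed in triple mutant buds, 1525 up and 1773 down, but only 80 and 310 changed at least 2-fold. Fitted with all 9 bud libraries together, 0 genes passed and every named call here ended. In that model the 3 genotypes share 1 spread per gene. Quintuple mutant bud replicates lay further apart than triple ones (chi-square per gene 34.2 to 201 and 7.6 to 12). The same model raised the quintuple mutant count from 464 to 3870, so its counts depend on the spread of the other mutant. In the 6 libraries 6696 genes had an unadjusted p under 0.05, DESeq2 gave 3639, and blocks for replicate number left 802.

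Quintuple mutant rosette buds were compared with wild-type buds with the same question. Of the 3 mutant libraries replicate 1 stood apart, correlating at 0.954 and 0.913 with replicates 2 and 3 (0.98 between those) and at 0.97 to 0.972 with wild-type buds. No S1 gene passed, although bZIP1 stood at 4.89 ± 0.813 CPM in wild type and 46.0 ± 31.8 in the mutant (log2 3.23 ± 0.66, adjusted p = 0.0563), with bZIP53 at 0.65 ± 0.17, bZIP2 at 0.27 ± 0.14, bZIP44 at 0.06 ± 0.25 and bZIP11 at -0.04 ± 0.29. SWEET12 rose from 1.8 ± 1.12 to 40 ± 28.1 CPM (4.46 ± 0.80), while SWEET11 (2.1 ± 0.49), SWEET13 (-1.91 ± 0.38), PRODH1 (-2.08 ± 0.40), GAT1_2.1 (0.99 ± 0.27), ASN1 (0.18 ± 0.36) and BRC1 (-0.78 ± 0.19) did not pass. Amino acid carriers UMAMIT28, AAP3 (AT1G77380) and LHT1 (AT5G40780) rose 5.41-fold, 3.71-fold and 3.41-fold, and the nitrate transporter NRT1.7 (AT1G69870) was 3.05-fold lower. Amino acid and nitrate transporter genes rose in 3 of 22 cases and fell in 1, with 13 rises over the list alone (median 0.89, camera adjusted p = 4.86e-05, and 0.827 with an estimated correlation). Cold and dehydration genes KIN1 (AT5G15960), KIN2 and COR15A (AT2G42540) were 7.34-fold, 5.08-fold and 4.97-fold lower, 3 of the 16 members of the abscisic acid list (median -0.04 beside a mean of -0.42, 0.0101 and 0.827). The floral regulator LFY was 3.85-fold lower, and 1 of 12 floral identity genes passed (median -2.06, 6.91e-05 and 0.719).

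Growth and pigment lists of quintuple mutant buds passed with few single genes. Anthocyanin and flavonoid genes fell in 1 of 13 cases, CHI (AT3G55120) 3.32-fold, with 6 over the list alone (median -2.17, camera adjusted p = 1.68e-07, and 0.685 with an estimated correlation). Starch genes fell in 1 of 26, AMY3 (AT1G69830) 2.36-fold, with 10 over the list alone (median -0.61, 0.000174 and 0.685). Photosynthesis genes (0 of 23, median -1.67, 1.11e-09 and 0.780), cell cycle genes (0 of 15, median -0.68, 0.0078 and 0.926) and low energy marker genes (0 of 17, median 0.87, 0.0193 and 0.923) passed as lists without a single member passing. Senescence genes rose in 2 of 12, SAG13 (AT2G29350) 5.16-fold and SAG21 4.83-fold (7 over the list alone, 2.47e-05 and 0.649), and immune genes in 1 of 18, PBS3 (AT5G13320) 2.00-fold (0.0203 and 0.766). The largest falls included CYP96A15 (AT1G57750), a wax synthesis gene, 23.4-fold, and the largest rises CCOAMT (AT1G67980), 106-fold.

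Of 20417 tested genes 464 passed in quintuple mutant buds, 348 up and 116 down, 332 and 101 at least 2-fold, beside 6050 at an unadjusted p under 0.05 and 4026 with DESeq2. The share of calls that were rises was 75.0% with edgeR and 60.9% with DESeq2. Without quintuple mutant replicate 1, which stood apart, the balance was near even (5441 up and 5433 down). Single libraries left out gave between 0 and 10874 genes, and every named call here ended in at least 1 of these runs.

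Triple mutant sink leaves were compared with wild-type sink leaves to ask which genes of import and growth stood differently in young leaves. The S1 genes did not pass, with bZIP11 at 0.23 ± 0.33, bZIP53 at 0.16 ± 0.18, bZIP2 at -0.02 ± 0.15, bZIP44 at -0.18 ± 0.36 and bZIP1 at -0.35 ± 0.24. ASN1 rose from 5.55 ± 1.86 to 74.2 ± 65.2 CPM (log2 3.74 ± 0.63, adjusted p = 0.00457), and PRODH1 by 1.36 ± 0.26. SWEET11 (-0.30 ± 0.26), SWEET12 (-0.10 ± 0.32), SWEET13 (-0.58 ± 0.37) and GAT1_2.1 (0.53 ± 0.25) did not pass. Sugar carrier genes fell in 4 of 10 cases with no rise (median -0.33, camera adjusted p = 0.01, and 0.649 with an estimated correlation). The hexose carriers STP13 (AT5G26340), STP4 and STP1 (AT1G11260) were 4.59-fold, 2.16-fold and 1.90-fold lower, and the sucrose carrier SUC1 (AT1G71880) 1.53-fold. Amino acid and nitrate transporter genes fell in 8 of 18 cases (median -0.62, 4.87e-06 and 0.649), LHT1 from 47.5 ± 6.41 to 9.17 ± 1.85 CPM, CAT1 (AT4G21120) 3.25-fold and AMT1.1 2.03-fold. Glutamine synthetase GLN1.1 (AT5G37600) was 2.85-fold lower, and glutamate synthase GLT1 (AT5G53460) rose 2.07-fold.

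Most immune, senescence and dehydration genes fell in triple mutant sink leaves. Of 19 salicylic acid and immune genes 14 fell and none rose, 18 over the list alone (median -1.29, camera adjusted p = 4.70e-09, and 0.685 with an estimated correlation), including PAD4 (AT3G52430) from 117 ± 26.3 to 44.3 ± 3.86 CPM, SARD1 2.45-fold and EDS1 (AT3G48090) 1.82-fold. The flagellin response kinase gene FRK1 (AT2G19190) was 16.8-fold lower. Senescence genes fell in 7 of 11 cases (median -0.90, 2.41e-06 and 0.649), the NAC regulators ORE1 and NAP by 23.9-fold and 6.85-fold, and the chlorophyll breakdown gene SGR1 (AT4G22920) was 1.95-fold lower. Abscisic acid and dehydration genes fell in 9 of 14, 12 over the list alone with 1 rise (2.32e-05 and 0.649), RD29A 2.93-fold, RAB18 (AT5G66400) 2.85-fold and COR47 (AT1G20440) 2.5-fold. Heat shock genes, listed to mark the harvest, fell in 2 of 4 (median -1.68, 0.000829 and 0.649), HSP90.1 (AT5G52640) 6.14-fold and HSFA2 (AT2G26150) 5.88-fold. Cytokinin response genes rose in 5 of 10 (0.00209 and 0.649), with ARR6, ARR7 and ARR5 (AT3G48100) up 5.57-fold, 2.85-fold and 2.36-fold. MCM2 rose 1.81-fold and MCM5 1.72-fold, 2 of the 4 rises among 15 cell cycle genes, a list that did not pass (0.325). Defensin genes PDF1.3 and PDF1.2 rose 19.2-fold and 7.29-fold.

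Of 18888 tested genes 4621 passed in triple mutant sink leaves, 2336 up and 2285 down, with 517 and 706 at least 2-fold. The balance turned in several settings, among them DESeq2 size factors (2166 up and 2420 down). Analysed with all 9 libraries of the tissue the count was 2507, and single libraries left out gave 2627 to 4535.

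Quintuple mutant sink leaves were compared with wild-type sink leaves with the same question. bZIP2 fell from 77.5 ± 15.9 to 46.8 ± 5.76 CPM (log2 -0.73 ± 0.18, adjusted p = 0.0246), and bZIP1 (1.41 ± 0.54), bZIP53 (0.06 ± 0.21), bZIP11 (-0.14 ± 0.34) and bZIP44 (-0.32 ± 0.47) did not pass. SWEET11 rose from 182 ± 43.4 to 323 ± 77.3 CPM and SWEET13 from 12.2 ± 5.02 to 24.9 ± 4.76, while SWEET12 (0.80 ± 0.33), ASN1 (1.48 ± 0.77) and GAT1_2.1 (0.58 ± 0.29) did not pass. PRODH1 fell from 19.5 ± 2.33 to 9.03 ± 1.89 CPM. Photosynthesis genes fell in 22 of 23 cases, 23 over the list alone (median -1.45, camera adjusted p = 7.16e-28, and 0.649 with an estimated correlation). LHCB6 (AT1G15820), LHCA1 (AT3G54890) and LHCB1.2 (AT1G29910), which encode light harvesting proteins, were 3.42-fold, 3.31-fold and 3.00-fold lower, and the Rubisco small subunit gene RBCS2B (AT5G38420) 3.14-fold. Starch genes fell in 12 of 25, 15 over the list alone (median -0.54, 1.09e-05 and 0.649), the starch synthase gene SS1 (AT5G24300) 2.34-fold and the ADP-glucose pyrophosphorylase gene APS1 (AT5G48300) 2.24-fold. The plastid nitrogen assimilation genes GLN2 (AT5G35630) and GLU1 (AT5G04140) were 2.45-fold and 2.06-fold lower.

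Most measured pigment genes of quintuple mutant sink leaves fell. Flavonoid genes FLS1 (AT5G08640), CHS (AT5G13930) and F3H (AT3G51240) were 9.77-fold, 9.34-fold and 6.02-fold lower, with 7 of 11 list members down (median -2.12, camera adjusted p = 1.02e-05, and 0.649 with an estimated correlation). CYP86A1 (AT5G58860) and FACT (AT5G63560), both known for suberin synthesis, were among the largest rises and went from no counts to 2.28 ± 0.884 and 2.24 ± 1.28 CPM, at least 59.8-fold and 59.1-fold, with no suberin list tested. SEP1 (AT5G15800) was 36.6-fold lower. Heat shock and clock genes were listed to mark the harvest, and a difference at harvest was not tested. Heat shock genes fell in 2 of 5 (0.0326 and 0.649), HSP18.2 (AT5G59720) 6.99-fold. Clock genes rose in 5 of 12 and fell in 1 without passing as a list (0.329), TOC1 (AT5G61380) 4.14-fold, and auxin response genes fell in 2 of 11 (0.794). SAG21 rose 3.13-fold and ORE1 3.05-fold, 2 of 3 rises among 11 senescence genes (0.102), and vascular genes fell in 3 of 11 (0.0519).

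Of 19198 tested genes 4769 passed in quintuple mutant sink leaves, 2285 up and 2484 down, with 969 and 1137 at least 2-fold. Blocks for replicate number gave 2675 genes, and single libraries left out gave 1774 to 5326.

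Triple mutant source leaves were compared with wild-type source leaves to ask which genes of export and leaf ageing stood differently. No S1 gene passed, with bZIP11 at 0.22 ± 0.17, bZIP44 at 0.03 ± 0.31, bZIP53 at 0.01 ± 0.18, bZIP2 at -0.42 ± 0.15 and bZIP1 at -0.66 ± 0.28. ASN1 rose from 4.49 ± 3.08 to 26.5 ± 17.5 CPM (log2 2.56 ± 0.61, adjusted p = 0.023), and SWEET11 (0.17 ± 0.15), SWEET12 (0.10 ± 0.19), SWEET13 (0.14 ± 0.19), GAT1_2.1 (0.01 ± 0.22) and PRODH1 (0.08 ± 0.18) did not pass. Of the C group bZIP genes, whose products pair with S1 proteins, bZIP63 (AT5G28770) fell from 24.8 ± 5.18 to 13.5 ± 4.54 CPM and bZIP10 (AT4G02640) from 47.1 ± 2.87 to 34.1 ± 1.45, while bZIP9 (AT5G24800; -0.55 ± 0.18) and bZIP25 (AT3G54620; -0.17 ± 0.12) did not pass (list median -0.51, camera adjusted p = 0.0442, and 0.649 with an estimated correlation). Cytokinin response genes rose in 5 of 10 cases, 7 over the list alone (median 0.76, 3.58e-07 and 0.649), with the type A response regulators ARR6, ARR15, ARR7 and ARR5 up 20.2-fold, 8.29-fold, 5.28-fold and 4.11-fold. The growth genes EXO (AT4G08950), PHI-1 (AT1G35140) and EXLA1 (AT3G45970) were 11.9-fold, 5.98-fold and 5.10-fold lower. PHI-1 is the locus that was left out of the low energy marker list under the name EXO-L.

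Ageing and nitrogen genes of triple mutant source leaves included falls and rises. Senescence genes fell in 6 of 12 cases with none higher (median -0.55, camera adjusted p = 0.00109, and 0.685 with an estimated correlation), ORE1 3.81-fold, NAP 3.66-fold and the chlorophyll breakdown genes PPH (AT5G13800) and PAO (AT3G44880) 1.71-fold each. Abscisic acid and dehydration genes fell in 4 of 16, 7 over the list alone (0.00213 and 0.685), RAB18 3.19-fold and COR47 2.47-fold. Immune genes fell in 6 of 19 (0.0432 and 0.923), NIMIN1 (AT1G02450) 3.19-fold and WAK1 1.54-fold. Amino acid and nitrate transporter genes fell in 6 of 21 (median -0.13, 0.0273 and 0.879), LHT1 2.18-fold and AAP4 1.84-fold. GLT1 rose from 202 ± 16.1 to 503 ± 95.1 CPM, ASN2 (AT5G65010) 2.37-fold and GDH2 2.07-fold, whereas GLN1.1 was 1.83-fold lower, in a nitrogen metabolism list with 6 of 26 up and 1 down that did not pass (0.197). Starch genes fell in 3 of 25 cases and rose in 1 without passing as a list (0.199), the beta-amylase gene BAM1 (AT3G23920) from 337 ± 19.8 to 164 ± 15.9 CPM.

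Of 18795 tested genes 3076 passed in triple mutant source leaves, 1665 up and 1411 down, with 486 and 296 at least 2-fold. The count was 232 with all 9 libraries of the tissue, 1353 with replicate blocks, and 766 to 4022 with single libraries left out. Of 63 named calls 15 were kept in every setting.

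Quintuple mutant source leaves were compared with wild-type source leaves with the same question. bZIP2 fell from 87.7 ± 15.8 to 46.5 ± 9.99 CPM (log2 -0.91 ± 0.21, adjusted p = 0.0292) and bZIP53 rose from 36.1 ± 8.68 to 58.8 ± 6.81 (0.70 ± 0.20), while bZIP1 (0.83 ± 0.27), bZIP44 (0.64 ± 0.69) and bZIP11 (-0.25 ± 0.24) did not pass. PRODH1 fell from 21.4 ± 1.41 to 13.7 ± 1.89 CPM and its relative PRODH2 (AT5G38710) rose 7.42-fold. SWEET11 (0.72 ± 0.35), SWEET12 (0.58 ± 0.43), SWEET13 (0.89 ± 0.37), ASN1 (-1.92 ± 0.69) and GAT1_2.1 (-0.06 ± 0.24) did not pass. Photosynthesis genes fell in 7 of 23 cases, 18 over the list alone (median -1.53, camera adjusted p = 8.10e-09, and 0.790 with an estimated correlation), LHCA1 3.48-fold and LHCB2.1 (AT2G05100) 2.94-fold. Starch genes fell in 9 of 25 and rose in 1 (median -0.65, 6.56e-05 and 0.649), the phosphatase gene SEX4 (AT3G52180) 2.48-fold, while the plastid glucose 6-phosphate carrier GPT2 (AT1G61800) rose 8.07-fold. Vascular genes fell in 6 of 10 (median -1.23, 5.29e-07 and 0.649), with the xylem protease XCP1 (AT4G35350) 6.61-fold and the cellulose synthase genes IRX1 (AT4G18780) and IRX3 (AT5G17420) 4.38-fold and 4.19-fold lower. Flavonoid genes fell in 4 of 10, 7 over the list alone (0.000135 and 0.649), FLS1 22.7-fold and CHS 14.5-fold, and cell cycle genes in 3 of 11 (0.00407 and 0.649), KN (AT1G08560) 7.49-fold.

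Immune and phosphate lists of quintuple mutant source leaves included rises only. Of 19 salicylic acid and immune genes 9 rose and none fell, 11 over the list alone (median 0.89, camera adjusted p = 2.91e-05, and 0.685 with an estimated correlation), the camalexin gene PAD3 (AT3G26830) 6.54-fold, PR1 (AT2G14610) from 392 ± 271 to 2070 ± 386 CPM and CBP60G (AT5G26920) 2.69-fold. Phosphate starvation genes rose in 3 of 7, 6 over the list alone (median 3.87, 0.00415 and 0.827), with the phosphate transporter PHT1.4 (AT2G38940) from 1.55 ± 0.420 to 37.2 ± 28.2 CPM and the phosphate sensor SPX1 (AT5G20150) from 7.04 ± 3.85 to 121 ± 89.4. Senescence genes rose in 3 of 12 (0.0404 and 0.923), SAG13 5.52-fold and SAG21 2.74-fold. The amino acid carriers CAT1 and AAP3 rose 4.79-fold and 4.02-fold in a transporter list that did not pass (0.725). The egg cell gene EC1.1 (AT1G76750), which shares 46.9% of its length with a neighbour, went from no counts to 2.2 ± 0.635 CPM, at least 53.7-fold. Defensin PDF1.2B (AT2G26020) was 24.2-fold lower.

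Of 18907 tested genes 3411 passed in quintuple mutant source leaves, 1738 up and 1673 down (1701 and 1701 with DESeq2 size factors), with 983 and 1004 at least 2-fold. DESeq2 gave 5383 genes, replicate blocks 25, and single libraries left out 29 to 7869, and 2 of 69 named calls were kept in every setting.

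**Figure D2:**
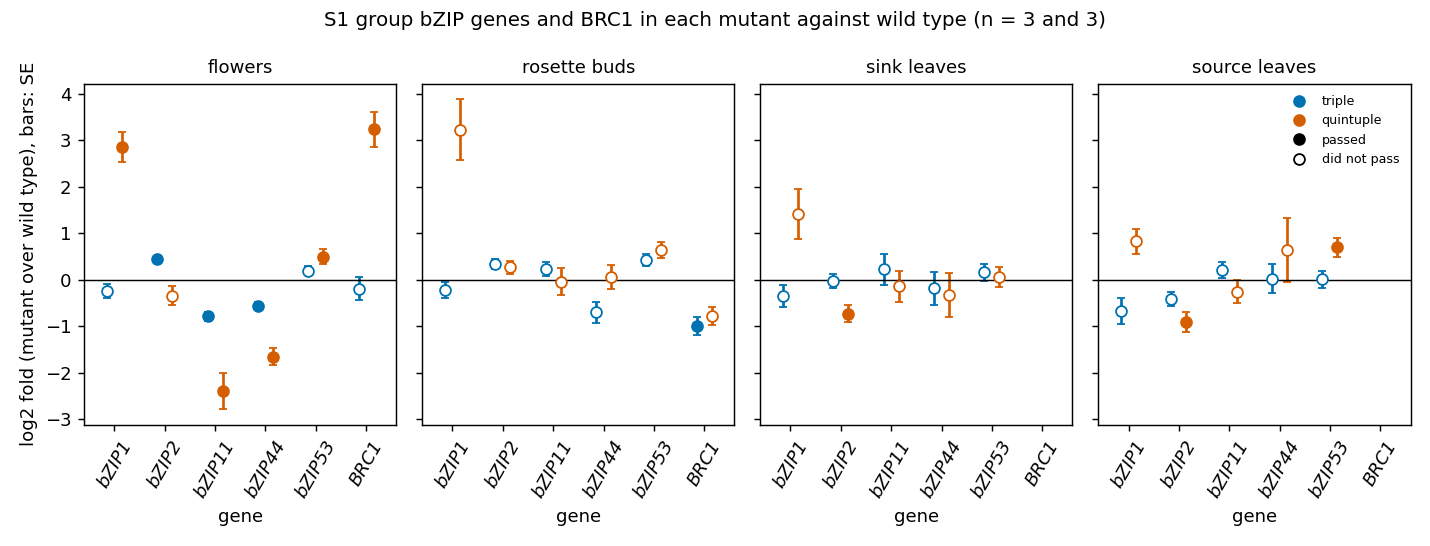
Log2 folds of the 5 S1 bZIP genes and BRC1 in each mutant against wild type, with SE bars and filled points for genes that passed (n = 3 and 3). BRC1 was too low for testing in leaves, fell in triple mutant buds (-0.99) and rose in quintuple mutant flowers (3.24).

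**Figure D3:**
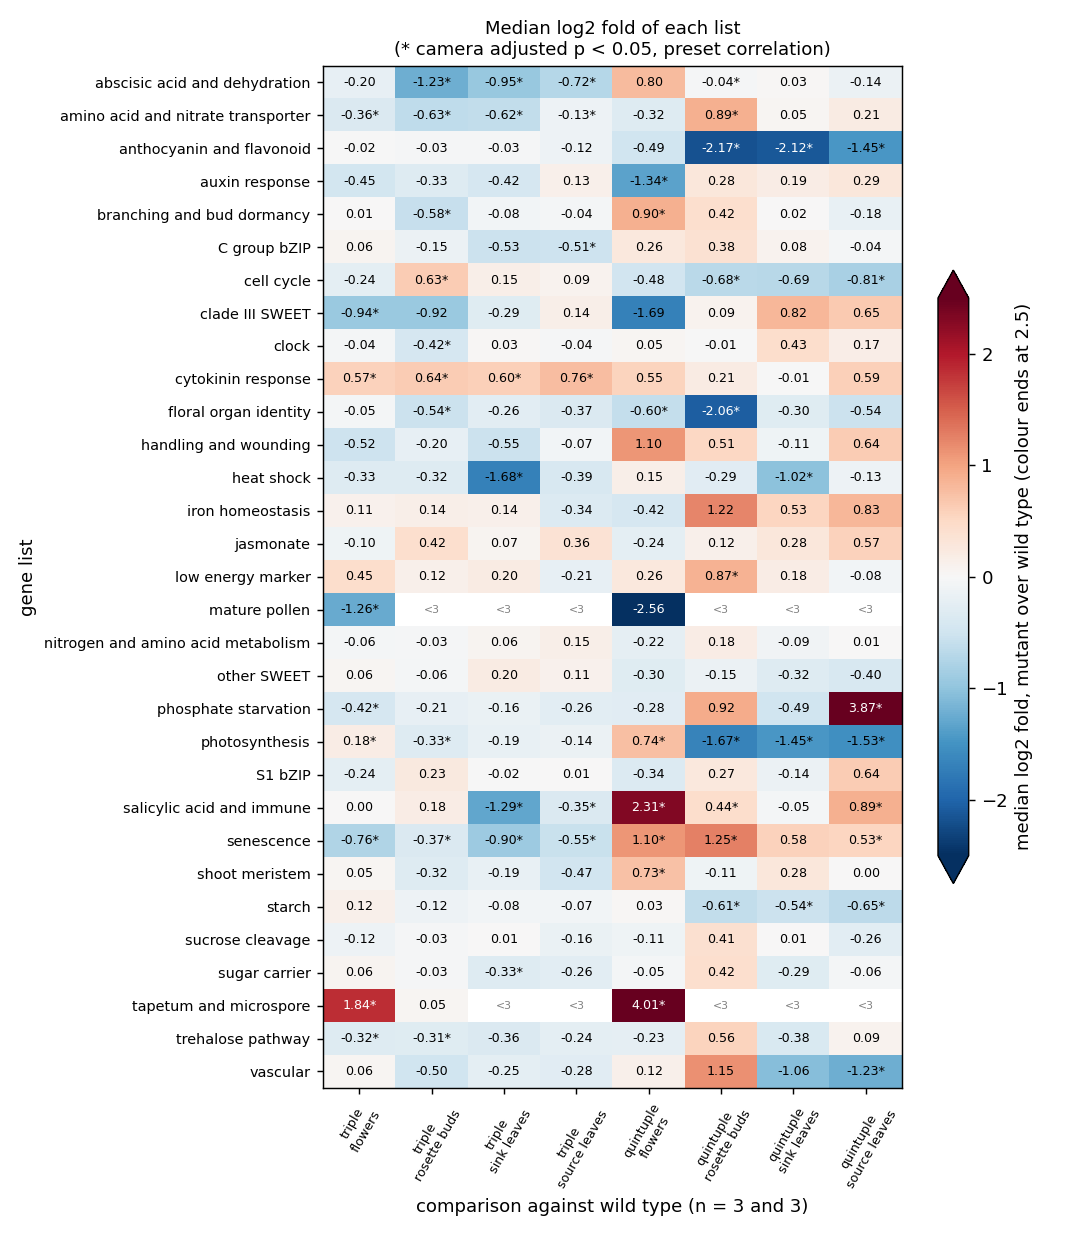
Median log2 fold of each gene list in the 8 comparisons with wild type, with asterisks where camera with a preset correlation passed (n = 3 and 3). Tapetum genes of quintuple mutant flowers had the highest median (4.01) and mature pollen genes of the same flowers the lowest (-2.56), and lists with fewer than 3 measured members are marked <3. The 10 seed storage and maturation genes had fewer than 3 measured members in every comparison and were not tested.

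The mutants were compared with each other within each tissue to ask where the libraries labelled quintuple and triple mutant stood apart. The model of 9 libraries gave all genotypes 1 spread per gene, although quintuple mutant replicates lay further apart. In buds chi-square per gene was 34.2 to 201 in the quintuple mutant, 17.2 to 23.3 in wild type and 7.6 to 12 in the triple mutant. The SE and calls below may therefore understate the quintuple mutant spread. bZIP1 was higher in the quintuple than in the triple mutant in flowers (log2 3.13 ± 0.30), buds (3.44 ± 0.58), sink leaves (1.8 ± 0.49) and source leaves (1.48 ± 0.32). bZIP2 was lower in flowers (-0.74 ± 0.18) and sink leaves (-0.69 ± 0.15), bZIP11 in flowers (-1.58 ± 0.34), and bZIP44 lower in flowers (-1.05 ± 0.17) and higher in buds (0.76 ± 0.23). PRODH1 was lower in the quintuple mutant in every tissue, from 481 to 65.8 CPM in flowers and from 82.8 ± 7.06 to 8.24 ± 4.55 in buds, and ASN1 was 22.5-fold lower in source leaves. BRC1 was higher in flowers (3.46 ± 0.36) and did not pass in buds (0.20 ± 0.23). Largest differences included the beta-glucosidase gene BGLU31 (AT5G24540), at least 151-fold higher in flowers, WRKY61 (AT1G18860), at least 115-fold higher in sink leaves, and MIOX2 (AT2G19800), 11.6-fold lower in buds. The phospholipase gene NPC4 (AT3G03530), known from phosphate starvation, was 57.1-fold higher in source leaves, at 5.05 ± 6.80 CPM. Genes named in this comparison other than the S1 genes and the largest differences were picked after their values were seen.

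Lists separated the mutants in each tissue. Senescence genes were higher in the quintuple mutant in 12 of 12 cases in flowers (camera adjusted p = 6.06e-09, and 0.569 with an estimated correlation), 10 of 12 in buds (8.23e-07 and 0.569), 10 of 11 in sink leaves (2.94e-05 and 0.569) and 9 of 12 in source leaves (2.15e-05 and 0.626). Immune genes were higher in 18 of 19 in flowers (3.26e-08 and 0.569), 11 of 19 in sink leaves (0.000955 and 0.791) and 16 of 19 in source leaves (9.17e-09 and 0.569). Amino acid and nitrate transporter genes were higher in 20 of 22 and lower in 1 in buds (6.06e-09 and 0.569), LHT1 by 1.86 ± 0.29 and UMAMIT28 by 3.06 ± 0.42. Photosynthesis genes were lower in 22 of 23 in sink leaves (3.22e-16 and 0.569) and 19 of 23 in source leaves (5.79e-07 and 0.776), and higher in 11 of 23 in flowers (0.0109 and 0.877). Cell cycle genes were lower in 8 of 15 in buds (2.93e-05 and 0.776) and 7 of 14 in source leaves (0.00034 and 0.569). Tested genes past the threshold numbered 7518 of 22076 in flowers, 7931 of 20552 in buds, 8529 of 19465 in sink leaves and 6689 of 19206 in source leaves. Without triple mutant replicate 1 no bud gene passed, and analyses of the 6 mutant libraries alone gave 5006, 1554 and 3177 genes in flowers, buds and source leaves.

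Genes that passed in both mutants of a tissue were counted against the number expected if the calls were independent. In flowers 1101 genes rose in both (419 expected) and 2139 fell in both (647 expected), with 229 in opposite directions (1060 expected) and a correlation of log2 folds of 0.72. Source leaves had 193 shared rises (142 expected) and 346 shared falls (127 expected), and 68 opposite (270 expected, r = 0.32). In sink leaves 315 rose in both (262 expected), 401 fell in both (303 expected) and 448 stood opposite (566 expected, r = 0.08), and in buds the numbers were 17 (22), 66 (10.3) and 10 (34.5), with r = -0.069. These numbers depended on the calls. Shared calls in the same direction went from 3240 to 1399 in flowers, from 539 to 105 in source leaves and from 83 to 0 in buds with all 9 libraries. They went to 8 in source leaves with replicate blocks, and to between 11 and 858 in source leaves, 0 and 373 in buds and, from 716, 180 and 687 in sink leaves with single libraries left out. A difference in flower age common to both mutants was not tested and could add to the shared flower calls. Part of any excess may also come from the shared wild-type libraries, which are too few to be divided between the comparisons. In 5 simulations per tissue without any mutant effect the shared controls alone gave a mean correlation of 0.499 in flowers, 0.500 in buds, 0.511 in sink leaves and 0.501 in source leaves, but at most 2 called genes in any comparison, too few to show how many shared calls the controls add. Covariance of the log2 folds was 0.731 in flowers beside 0.0356 simulated, 0.135 beside 0.0481 in source leaves, 0.0336 beside 0.0464 in sink leaves and -0.0233 beside 0.0506 in buds. All simulated libraries, wild type included, had the same spread per gene, which sets a correlation near 0.500 in advance. Real wild-type replicates lay closer together than quintuple mutant ones (chi-square per gene 17.2 to 23.3 and 34.2 to 201 in buds). The simulated correlations and covariances may therefore overstate what the shared controls add.

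Differences of the mutant effect between tissues were tested across all libraries of a genotype and wild type, and the p values below are for any difference. The tissue pair that stood furthest apart, among tissues where the gene was tested against wild type, is named beside them. For the triple mutant 3687 of 22454 genes passed and for the quintuple 5294 of 22823. The triple mutant effect on ASN1 was higher in sink leaves than in buds (log2 difference 4.42, interaction adjusted p = 0.000757), and the effect on PRODH1 higher in sink leaves than in flowers (1.48, 0.00373). STP4 rose in flowers (1.25) and fell in sink leaves (-1.11) in the separate tests of each tissue, with a difference of 2.34 in the model of 24 libraries (2.82e-07). For the quintuple mutant the BRC1 effect was higher in flowers than in buds by 4.03 (0.00373), that on SWEET13 higher in sink leaves than in buds by 2.93 (0.00129), and that on PRODH1 lower in flowers than in source leaves by 2.43 (0.00262). Effects on bZIP11 were lower in flowers than in buds by 1.02 in the triple (0.0289) and 2.37 in the quintuple mutant (0.0039). SWEET11 (0.199), ASN1 (0.0746), bZIP1 (0.0631) and bZIP53 (0.234) did not pass in the quintuple mutant, nor SWEET13 (0.0676), SWEET11 (0.145) and bZIP44 (0.345) in the triple.

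A set of genes changed in the same direction in all 4 tissues. In the triple mutant 166 of 17945 genes rose and 168 fell everywhere, where 1.68 and 1.75 were expected from independent calls, and in the quintuple mutant 89 of 18277 rose and 26 fell (0.638 and 0.165 expected). These sets depended on the calls of each tissue, and were recounted in other settings after the values had been seen. With all 9 libraries of each tissue 0 genes were left in the triple and 703 in the quintuple mutant, with replicate blocks 96 and 3, and with single libraries left out 148 to 372 and 0 to 571. The balance of rises and falls in the quintuple mutant moved too. It was 390 and 279 with DESeq2, 438 and 265 with all 9 libraries, and 341 and 230 without quintuple mutant bud replicate 1. The vacuolar protease gene GAMMA-VPE (AT4G32940) fell in triple mutant flowers (-1.03 ± 0.20), buds (-1.18 ± 0.09), sink leaves (-2.06 ± 0.29) and source leaves (-1.23 ± 0.14). BAM1 fell by 0.59, 0.66, 0.99 and 1.05 in the same order, formate dehydrogenase FDH (AT5G14780) by 0.55, 0.63, 1.17 and 0.90, and PDE340 (AT5G08610) rose by 0.38, 0.74, 1.79 and 1.74. In the quintuple mutant the CCAAT-binding factor gene NF-YA2 (AT3G05690) rose in flowers (2.79 ± 0.22), buds (1.22 ± 0.14), sink leaves (1.90 ± 0.20) and source leaves (2.60 ± 0.19). The lipase gene PLA2A (AT2G26560) rose by 4.74, 4.18, 1.71 and 2.65, the camalexin pathway gene CYP71A12 (AT2G30750) by 3.72, 3.14, 2.07 and 2.79, and the endoglucanase GH9B8 (AT2G32990) fell by 1.47, 1.42, 2.21 and 4.51.

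Tissues shared calls to different extents. In the triple mutant sink and source leaves had 1144 shared rises and 854 shared falls (205 and 173 expected) with 6 opposite, and buds and sink leaves 841 and 878 (183 and 200 expected) with 14 opposite. In the quintuple mutant sink and source leaves had 826 and 1043 (201 and 217 expected) with 4 opposite, while flowers and sink leaves had 904 and 637 (454 and 354 expected) with 482 opposite (820 expected). Each tissue had its own wild-type libraries, so these counts share none. They cannot exceed the calls of either tissue, which fell to 25 in quintuple mutant source leaves with replicate blocks and to 29, 52 and 203 without 1 of the wild-type libraries, and to 0 in triple mutant buds and 232 in triple mutant source leaves with all 9 libraries.

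Wild-type sink leaves were compared with wild-type source leaves to give a scale for leaf age. bZIP53 stood higher in sink leaves (log2 0.63 ± 0.18, adjusted p = 0.0228), and bZIP44 (0.62 ± 0.31), bZIP11 (0.01 ± 0.20), bZIP2 (-0.06 ± 0.15) and bZIP1 (-0.30 ± 0.22) did not pass. Division gene CYCD3.1 (AT4G34160) stood at 8.21 CPM in sink and 2.80 in source leaves, CHS at 379 and 60.4, XCP1 at 26.9 and 5.82, and ORE1 at 9.40 and 32.7. Cell cycle genes were higher in sink leaves in 11 of 15 cases (median 1.21, camera adjusted p = 6.86e-08, and 0.136 with an estimated correlation), photosynthesis genes in 18 of 23 (0.83, 2.61e-16 and 0.495), vascular genes in 8 of 11 (1.37, 2.27e-07 and 0.495) and flavonoid genes in 7 of 13 (0.99, 0.000618 and 0.334). Senescence genes were lower in 6 of 12 (-0.52, 0.000162 and 0.495). Of 21987 tested genes 4892 passed, 2912 higher and 1980 lower in sink leaves. Genes past this test were then counted by the direction of the mutant change. In quintuple mutant sink leaves 85.8% of 4722 such genes changed in the source direction, against 65.5 to 67.7% in simulations without a mutant effect, and in quintuple mutant source leaves 73.2% of 4485 changed in the source direction, against 30.5 to 32.7%. The shares in the triple mutant were 37.2% in sink leaves (65.9 to 66.8% simulated) and 36.3% in source leaves (31.8 to 33.1%). All simulated libraries had the same spread per gene, and genes were drawn independently. Real wild-type source leaf replicates lay closer together than quintuple mutant ones (chi-square per gene 18.3 to 28 and 68.4 to 170). The simulated shares may therefore overstate the effect of the shared wild-type libraries. The small gap in triple mutant source leaves decides nothing.

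**Figure D4:**
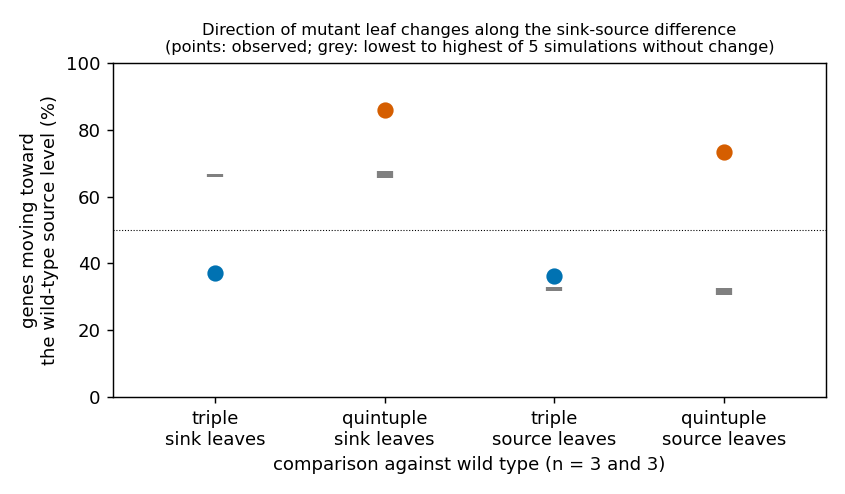
Share of genes differing between wild-type sink and source leaves that moved in the source direction in each mutant (n = 3 per group). Grey marks the range of 5 simulations that had no mutant effect and the same spread in all genotypes. Shares were 85.8% and 73.2% in quintuple mutant sink and source leaves and 37.2% and 36.3% in the triple mutant.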

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

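The mutant effect differed between tissues for 3687 genes in the triple and 5294 in the quintuple mutant, by a test of the difference itself. Values below are log2 differences between the 2 tissues that stood furthest apart, among tissues where the gene was tested against wild type. BRC1 was too low for testing in leaves, so flowers and buds were its only pair. Its test of any difference still covered all 4 tissues. In the triple mutant they were 5.23 for AT4G37900 (higher in flowers than in sink leaves), 2.06 for IMPL2 (AT4G39120; sink leaves over flowers), 2.35 for AT1G11780 and 2.07 for AT1G04540 (source leaves over flowers) and 2.34 for STP4 (flowers over sink leaves). Of the genes fixed in advance, bZIP2 differed by 0.83 (flowers over source leaves), bZIP11 by 1.02 (buds over flowers), ASN1 by 4.42 (sink leaves over buds), PRODH1 by 1.48 (sink leaves over flowers) and BRC1 by 0.80 (flowers over buds, where the test of that pair alone did not pass, adjusted p = 0.201). In the quintuple mutant the smallest p values were those of GAE4 (AT2G45310; 2.78) and the overlapping AT2G45315 (2.77), both sink leaves over flowers, GRP-3 (AT2G05520; 4.65) and ENGase85A (AT5G05460; 3.08), both flowers over source leaves, and CNGC11 (AT2G46440; 3.07, flowers over buds). Fixed genes differed by 1.13 for bZIP2 (buds over source leaves), 2.37 for bZIP11 (buds over flowers), 2.36 for bZIP44 (source leaves over flowers), 3.79 for SWEET12 (buds over source leaves), 2.93 for SWEET13 (sink leaves over buds), 1.60 for GAT1_2.1 (buds over flowers), 2.43 for PRODH1 (source leaves over flowers) and 4.03 for BRC1 (flowers over buds). No group had the 4 or more libraries that a test for outlying samples needs.

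The splits and the test near the S1 loci were planned before results were seen, and the bud, flower and leaf patterns below were picked after list results were seen. In each comparison of 3 with 3 libraries 1 split of 10, the real one, reached its own count. The highest other counts were 0, except for 1 in triple mutant buds and 4 between wild-type leaves, and 10 splits are too few for a share under 0.05. For the tissue tests 1 of 30 splits, the real one, reached the count, with highest others of 282 in the triple and 936 in the quintuple mutant. Calls were not enriched within 1 Mb of the S1 loci, with a highest upper 95% bound of the odds ratio of 1.14. Most tested genes lie outside these windows, in triple mutant flowers 19186 beside 2101 within them. Sequence differences within the windows could therefore not give most calls, whatever the odds ratios, so that point was given in advance. The labels do not name the mutated loci, and windows around unmutated loci may dilute an enrichment in the triple mutant. Linked differences as a source of some calls stay possible.

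The first quintuple mutant bud library stood apart from its group (r = 0.954 and 0.913, beside 0.97 to 0.972 with wild-type buds). Of 721 genes changed in one direction in the 3 other tissues, 82.4% lay beyond all wild-type bud libraries in that direction (89.7% in replicates 2 and 3), where 25% would by chance. Of 2273 such genes against the triple mutant 87.7% did (93.4% and 94.8%). A wild-type or a triple mutant library under the wrong label is excluded by these values, and no biological explanation was tested.

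Young anther, bud and meristem genes stood higher in quintuple mutant flowers. Of 9 genes at 50 CPM or more in wild-type buds and under 1 CPM in flowers, as scaled among the 12 wild-type libraries, 33.3% lay above wild-type flowers when scaled by library totals (median 0.174% of the bud level, highest 10.4%), and of 12 such leaf genes 83.3% (median 4.96%, highest 13.4%, beside 66.7% and 0.856% in the triple mutant). In a test added after these values were seen, 96.3% of the rising anther, branching and meristem genes would need more bud tissue, and 100% more leaf tissue, than the highest share shown by those bud and leaf genes (10.9% and 18.3% by the lower of the wild-type and mutant organ levels). Rosette bud tissue alone thereby cannot account for these rises in full, SMXL7 excepted (9.76% needed), nor can source leaf tissue alone. For tapetum genes, nearly absent from both organs (at least 260% of buds and 414% of leaves needed), this was given in advance. Other organs, sink leaves among them, were not tested as a source. Some leaf tissue in the libraries, which would bring leaf and photosynthesis genes, stays possible. A larger share of young flowers stays possible, as does a changed program at the same age. Tapetum genes had a median of 4.01 and mature pollen genes -2.56, a list that did not pass (camera adjusted p = 0.0817, 4 of 7 fell, 1 rose). The prediction for young flowers was written after the values were seen. Tapetum and mature pollen medians moved in the same directions in triple mutant flowers, so a larger share of young flowers stays possible there too.

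Leaf genes of the quintuple mutant shifted along the wild-type difference between sink and source leaves. In source leaves 73.2% of 4485 genes changed in the source direction, against 30.5 to 32.7% in simulations. This is what leaves further along that difference would give, and leaf age or position at harvest cannot be told from genotype here.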

How the results depend on the processing

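No gene called in the main analysis and again in another setting changed direction, a weak check because the settings use nearly the same libraries. Counts of genes past the threshold moved. Of the values for single genes and lists 0 reversed, 8881 kept their side of the threshold, 1361 lost it and 168 gained it. Models of all 9 libraries of a tissue gave 1638 genes in triple mutant flowers (5711 in the 6 libraries), 0 in triple mutant buds (3298, with 6696 at an unadjusted p under 0.05), 2507 in triple mutant sink leaves (4621) and 232 in triple mutant source leaves (3076), but 3870 in quintuple mutant buds (464) and 5300 in quintuple mutant source leaves (3411). These models share 1 spread per gene among the 3 genotypes, so their triple mutant counts carry the wider spread of the quintuple mutant libraries. Their quintuple mutant counts likewise carry the narrower spread of the other libraries. DESeq2 gave 4026 and 5383 in quintuple mutant buds and source leaves. With a replicate block the counts were 802 in triple and 258 in quintuple mutant buds, 2675 in quintuple mutant sink leaves (4769), and 1353 and 25 in triple and quintuple mutant source leaves. In no comparison were all 3 correlations of same-number libraries over 0.1, the limit set in advance (lowest -0.32, wild-type and triple mutant buds), so the replicates were not treated as pairs. In 2 cases each library correlated best with its own number, wild-type and triple mutant sink leaves (0.17, 0.04 and 0.16, others at most 0.02) and triple and quintuple mutant source leaves (0.14, 0.08 and 0.29, others at most 0.05). With single libraries left out the counts ranged from 3957 to 5140 in triple and 5541 to 11184 in quintuple mutant flowers, 1148 to 2942 and 0 to 10874 in buds, 2627 to 4535 and 1774 to 5326 in sink leaves, and 766 to 4022 and 29 to 7869 in source leaves. The highest quintuple counts came without quintuple replicate 1 in buds and source leaves, and in flowers without replicate 3, which correlated at 0.941 and 0.923 with the others (0.977 between those). In source leaves the main analysis gave fewer rises than falls in the quintuple against the triple mutant (3176 and 3513). Most other settings gave more rises, among them DESeq2 size factors (3434 and 3262), no organelle genes (3564 and 3104), DESeq2 (3926 and 3855) and the 6 mutant libraries alone (1973 and 1204). More falls came with no low count filter, with replicate blocks, and without triple replicate 3 or quintuple replicate 1. In triple mutant buds more genes rose than fell without wild-type replicate 2 (1526 and 1416, against 1525 and 1773). For the quintuple against the triple mutant, the 6 mutant libraries alone gave 5006 in flowers (7518), 1554 in buds (7931) and 3177 in source leaves (6689), and single libraries left out gave 4796 to 10137, 0 to 13854 and 2456 to 9898. Genes called in both mutants in the same direction numbered 1399 in flowers (3240) and 105 in source leaves (539) with all 9 libraries, and 0 in buds (83). With DESeq2 they were 419 in buds and 819 in source leaves, with the replicate block 18 and 8, and with single libraries left out 2035 to 3656 in flowers, 0 to 373 in buds, 180 to 687 in sink leaves and 11 to 858 in source leaves. Genes changed in one direction in all 4 tissues, recounted after seeing the data, numbered 334 in the triple and 115 in the quintuple mutant, 346 and 669 with DESeq2, 96 and 3 with the replicate block, 0 and 703 with all 9 libraries, and 148 to 372 and 0 to 571 with single libraries left out. Of the gene list tests 62 passed with the preset correlation, 59 to 69 with single libraries left out, and 0 with an estimated correlation. Odds ratios of a call near against away from the S1 loci in quintuple mutant buds were 0.665 at 1 Mb, 0.705 at 0.2 Mb and 0.892 at 3 Mb. Every named call in buds of either mutant ended in at least 1 setting, as did 48 of 63 in triple and 67 of 69 in quintuple mutant source leaves, while 108 of 130 in quintuple mutant flowers were kept. Beyond the shared spread of the 9-library models, no cause was examined.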

Other observations

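Some list members set the tissues of wild type apart before any mutant is considered, and were picked after their values were seen. The petal and stamen gene PI (AT5G20240) stood at 89.3 ± 2.3 CPM in flowers and 4.09 ± 0.588 in buds, and SEP3 (AT1G24260) at 61.2 ± 1.77 and 2.24 ± 0.216. The mitotic genes CYCB1.1 (AT4G37490) and CDKB1.1 (AT3G54180) stood at 11.6 ± 0.570 and 8.00 ± 0.529 CPM in flowers, 8.48 ± 1.37 and 6.62 ± 0.338 in buds, 0.965 ± 0.0812 and 1.08 ± 0.324 in sink leaves and 0.667 ± 0.255 and 0.479 ± 0.212 in source leaves. The median of 23 photosynthesis genes was 7290 CPM in sink leaves, 3900 in source leaves, 1250 in buds and 650 in flowers (n = 3 libraries per tissue).

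One hypothesis was tested for the leaves, that quintuple mutant source leaves stand further along the difference between wild-type sink and source leaves. The share in that direction (73.2%) lay above the simulated shares (30.5 to 32.7%), and in sink leaves 85.8% changed in the source direction beside 65.5 to 67.7% simulated. Leaves of known age and position from each genotype, sampled on the same day, would test whether age at harvest could account for it.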
